A study of Homo sapiens with 2 samples.

How the data were processed

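RNA of SNU-182 cells, an established human hepatocellular carcinoma line, was measured on an Illumina expression bead array after transfection with a control siRNA or with an siRNA against SIRT1, which encodes an NAD-dependent protein deacetylase. Per the labels' protocols, total RNA from 3 independent extractions was mixed in equal amounts for each condition, labelled with biotin as cRNA and hybridised, so that each condition was 1 pool on 1 array. Groups were taken from the labelled transfection. The pooling averages the extractions and leaves no value for the spread between them. No p-value or standard error between conditions was therefore computed, and every comparison is a difference between these 2 arrays.

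The deposited table gave a signal intensity and a detection p-value for 47229 probes on each array. Although its name calls it non-normalized, the sorted signal intensities deposited by the authors were identical on both arrays (largest difference 0), as quantile normalization leaves them. The signals were linear and had no background subtracted: their lowest value was 36.0 and the median signal of probes with a detection p-value close to the middle of its range was 104 on the control siRNA array and 105 on the SIRT1 siRNA array. The deposited detection p-values moved in steps of 0.0013, which corresponds to 770 negative controls. A second table held the authors' log2 values, which equalled log2 of the signal to within 1e-06. The scanner software, the bead numbers and the bead standard errors were not given in the sources used here. Because the deposited values were already quantile normalized, a difference in the overall distribution of signal between the pools could not be recovered.

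Background was corrected with the normal-exponential model of limma 3.58.1 in R 4.3.3 (neqc), which infers the background from the detection p-values, with an offset of 16, followed by quantile normalization and log2. The design, written before the data were examined, assumed values that had not been normalized, so the normalization was run a second time on normalized values. All differences are SIRT1 siRNA minus control siRNA on this log2 scale, and the offset shrinks differences of dim probes. Probes were detected at a detection p-value under 0.01. Gene names came from the platform annotation by probe: 30111 probes had 1 symbol, 8 had several and 17110 were unnamed in the table used. Of the named probes, 30072 had a gene identifier in the RefSeq table of GRCh38.p14, and no symbol needed an update. A gene was represented by its brightest detected probe, and 9787 named genes were detected on at least 1 array. For a gene detected on 1 array only, the fold is a lower bound, written "at least": the brighter value against the higher of the dim probe's own value and the lowest normalized value among detected probes of that array. It is a bound on the background-corrected scale, and a fold of the uncorrected signals can be smaller. Counts and list medians used measured values as the design had set, and were repeated with such genes at their bounds, an alternative chosen after the data were seen.

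Genes were counted by size, at 2-fold and, as an alternative, 1.5-fold. As a guide to measurement error, the log2 difference was compared among probes of the same gene. The pooled SD was 0.20 over 2085 genes with 2 or more probes detected on both arrays, 0.23 among genes dimmer than the median and 0.17 among brighter genes. This SD holds probe noise and real differences between transcript variants, and nothing of the variation between cultures. The number of arrays limits the precision of every value.

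The gene lists, 38 in all, and the rule for naming genes were fixed in the same design: the siRNA target, the 15 highest and 15 lowest differences among genes detected on both arrays, up to 6 genes per direction detected on 1 array, and up to 4 members per list with the largest difference. Predicted loci, open reading frames and pseudogenes were counted and not named. The 36 lists with at least 4 detected members were compared by their median log2 difference with 10000 random lists of the same size drawn from 20 bins of mean intensity. A list was called apart below the 1st or above the 99th percentile. The percentile describes these 2 arrays and is not a p-value for the conditions. With 36 lists, 0.72 would lie beyond these limits by chance if genes varied independently. Genes of a list can vary together between any 2 cultures, so more lists can lie beyond the limits without an effect of the siRNA.

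The same code was tested on simulated arrays with 200 changed genes, run on 11021 detected genes. Changed genes were drawn from those with a probe detected on both arrays, and noise was independent between probes. The shares below therefore do not cover genes detected on 1 array only or genes that vary together. Simulated 4-fold rises were placed past 2-fold in 100% of 50 genes and 4-fold falls in 98.0% of 50. Simulated 2-fold rises had a median log2 difference of 0.95 and passed 2-fold in 36.0%, and 2-fold falls had -0.98 and passed in 46.0%. Genes simulated at exactly the limit fall on either side of it by noise, so these 2 shares do not measure how many real differences are found. Of 200 simulated lists of unchanged genes, 3.5% were called apart. Alternatives were no background correction, an offset of 50, median scaling, the authors' log2 values, other detection filters, the mean of a gene's probes and a 1.5-fold limit. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for the counts and lists, and matplotlib 3.10.9 for the plots. No genome sequence was used. The RefSeq table gave the chromosome and order of genes, and no coordinates are given because the build of the array design was not given in the sources used here.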

Results

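Gene expression was profiled in SNU-182 hepatocellular carcinoma cells to ask which transcripts differ when the deacetylase SIRT1 is knocked down, within a study of the oncogenic potential of SIRT1 in liver cancer. The data comprised 1 array of cells given control siRNA and 1 array of cells given SIRT1 siRNA, each from a pool of 3 RNA extractions. The control siRNA array detected 14999 of 47229 probes (31.8%) and the SIRT1 siRNA array 14895 (31.5%). There were no replicates, so no difference below could be set against the spread between cultures, and differences are described by their size alone.

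SIRT1 mRNA was lower after SIRT1 siRNA. Its 1 named probe gave a signal of 369 on the control siRNA array and 262 on the SIRT1 siRNA array, with detection on both. After background correction the log2 difference was -0.70, a level 1.62-fold lower than with control siRNA. Without background correction it was -0.49. The difference had the direction of the label and was larger than the SD among probes of one gene, 0.20 over all such genes and 0.23 among dimmer ones. The SD of log2 differences over all detected genes was 0.38, and 374 genes, SIRT1 among them, were at least 1.5-fold lower. Size alone therefore does not set SIRT1 apart from other genes. None of the other detected sirtuins was higher: SIRT2, a mainly cytoplasmic deacetylase, differed by -0.62, SIRT7 by -0.36 and SIRT6 by -0.29. A second SIRT2 probe, detected with control siRNA only, gave -0.87, a measured value that rests on a signal near background. Its uncorrected signals, 223 and 162, have no larger ratio than those of SIRT1. The sirtuin list had 5 detected members, of which 2 were at least 1.5-fold lower, and its median of -0.36 lay at the 2.08th percentile of random lists, inside the limits.

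The largest group difference was in interferon-stimulated genes, the antiviral genes that cells switch on in response to interferon. Of 30 listed genes 23 were detected, 22 of these were higher after SIRT1 siRNA, 10 by at least 2-fold and none lower by that size. Among them IFIT2, IFIT3, OASL, IFIH1 and HERC5 were detected only after SIRT1 siRNA, so detection itself favoured a higher value for these. Among all genes detected on both arrays, 56 were at least 2-fold higher, and 49 once this list was left out. IFI27 went from a signal of 1415 to 6808, a 5.07-fold higher level after background correction. IFIT1, which binds viral RNA, was 4.78-fold higher, OAS2, an oligoadenylate synthetase, 4.20-fold higher, EPSTI1 3.49-fold higher and the antiviral GTPase MX1 3.41-fold higher. IFIT3 was detected only after SIRT1 siRNA, at least 2.20-fold higher. To complete the count, and chosen after their values were seen, the ubiquitin-like modifier ISG15 was 2.40-fold and IFITM1 2.18-fold higher, the RNA sensor IFIH1 at least 2.45-fold and OASL at least 2.13-fold higher. The last 2 bounds hold for background-corrected values. Uncorrected signals of 156 and 318 for IFIH1 and of 163 and 288 for OASL have smaller ratios.

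The interferon-stimulated list had a median log2 difference of 0.85, against -0.18 to 0.14 for the central 95% of random lists, and none of 10000 random lists reached it. With genes detected on 1 array set to their bounds the median was 0.72, and without background correction it was 0.49. Members were unequal: IFI35 differed by -0.03 and XAF1 by 0.09, and the RNA sensor RIGI by 0.29, all chosen after their values were seen. Probes of IFI6, also chosen after its values were seen, disagreed, the brighter giving 0.18 and the other 1.79, and only the brighter entered the count. Of the leukocyte markers, 4 were detected on both arrays, with a median log2 difference of 0.50 in the same direction, which was not apart from random lists in 3 of the alternative settings.

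**Figure D1:**
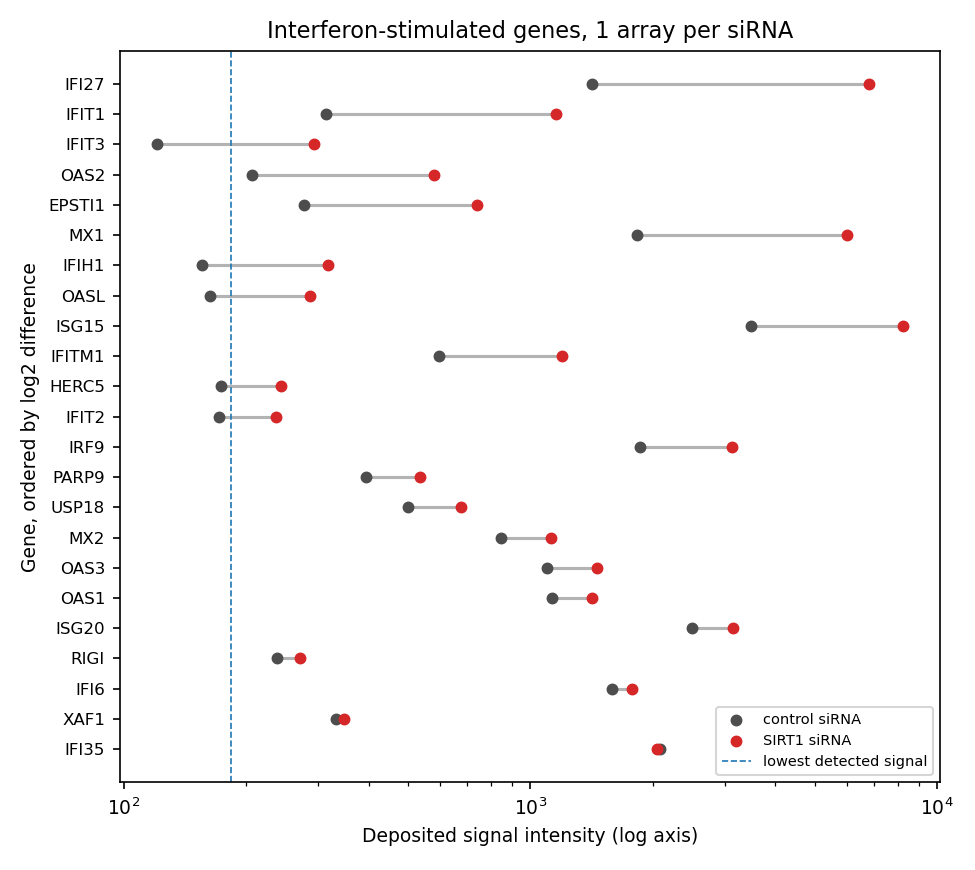
Deposited signal intensity (log axis) of the 23 detected interferon-stimulated genes on the control siRNA array (grey) and the SIRT1 siRNA array (red), 1 array each without error bars, ordered by the background-corrected log2 difference. All but IFI35 lie further right after SIRT1 siRNA, and the dashed line marks the lowest detected signal of 183.

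Over all 9787 detected named genes, 140 had measured values at least 2-fold higher after SIRT1 siRNA and 46 at least 2-fold lower, while 89.9% lay within 1.5-fold. Most of these, 84 and 37, were detected on 1 array only, so their measured fold rests on a signal near background. With such genes at their bounds, 79 were at least 2-fold higher and 13 at least 2-fold lower. Log2 values of the 2 arrays correlated at r = 0.98 across genes, which are not independent replicates, and the median gene differed by -0.03. Among genes detected on both arrays, 56 were at least 2-fold higher and 9 at least 2-fold lower, so that 86.2% of these differences were higher, against 75.3% by measured values among all detected genes. Without background correction the counts were 37 and 9.

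Beyond the interferon-stimulated genes, the highest differences among genes detected on both arrays were in SYT11, a membrane-trafficking synaptotagmin, at 4.28-fold, and GNG10, a G-protein gamma subunit, at 3.10-fold. A second GNG10 probe gave a log2 difference of 0.60 against 1.63, so this gene's size depends on the probe. The kinase gene SBK1 was 2.93-fold higher, CRBN, the substrate receptor of a ubiquitin ligase, 2.60-fold, and the immune-response regulator TCIM 2.59-fold. RIDA, a reactive-intermediate deaminase, was 2.56-fold, OXR1, an oxidation-resistance gene, 2.55-fold, the carbonyl reductase CBR4 2.47-fold, the translation initiation factor subunit EIF3E 2.46-fold and ANKRD46 2.45-fold higher. Without background correction CRBN (1.85-fold), OXR1 (1.82-fold), CBR4 (1.86-fold) and ANKRD46 (1.89-fold) were under 2-fold. EIF3E was bright, with a signal of 3523 against 8536. Among genes detected only after SIRT1 siRNA, the cytokine LTB, a member of the TNF family, was at least 3.32-fold higher. A second LTB probe was not detected on either array. MIX23 was at least 3.18-fold, ZCCHC12 at least 2.84-fold, PIGK at least 2.82-fold, RNF170 at least 2.65-fold and the small nucleolar RNA gene SNORA25 at least 2.56-fold higher. These bounds hold for background-corrected values: uncorrected signals gave 2.27-fold for MIX23, 2.12-fold for PIGK, 2.24-fold for SNORA25 and 2.0-fold for RNF170.

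Among genes detected on both arrays, 9 were at least 2-fold lower after SIRT1 siRNA, of which LYVE1, IGFBP1, ITGA5 and VPS25 were so without background correction too. LYVE1, a hyaluronan receptor, was 3.12-fold lower, with signals of 540 and 235. IGFBP1, a liver-secreted IGF-binding protein, was 2.75-fold lower and ITGA5, the alpha chain of the fibronectin receptor, 2.71-fold lower. The organic anion transporter SLC22A11 and the glycerol-phosphate dehydrogenase GPD1 were each 2.27-fold lower, PHLDA2 2.22-fold, the neurotensin receptor NTSR1 2.16-fold, the endosomal sorting subunit VPS25 2.14-fold and the PI3-kinase subunit PIK3CB 2.05-fold lower. VPS25 was bright, at 3368 against 1621, and its second probe gave a log2 difference of -0.76. NOL3, RUSC2, GPRC5A, AKAP12, AVL9 and SLC51B lay just inside 2-fold, between -0.99 and -0.97. Both detected probes of AVL9 gave close values, -0.97 and -0.95, whereas those of NOL3 gave -0.99 and -0.31. Of genes detected only with control siRNA, the poly(A) polymerase family member TENT5B was at least 4.25-fold lower after SIRT1 siRNA, the cystine transporter subunit SLC7A11 at least 2.61-fold, CYP1A1, a xenobiotic-metabolising cytochrome P450, at least 2.5-fold, PHYHD1 at least 2.23-fold, AP4M1 at least 1.81-fold and ELAPOR1 at least 1.81-fold lower. Here too the bounds depend on the correction, and uncorrected signals gave 2.88-fold for TENT5B, 2.12-fold for SLC7A11 and less for the other 4.

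**Figure D2:**
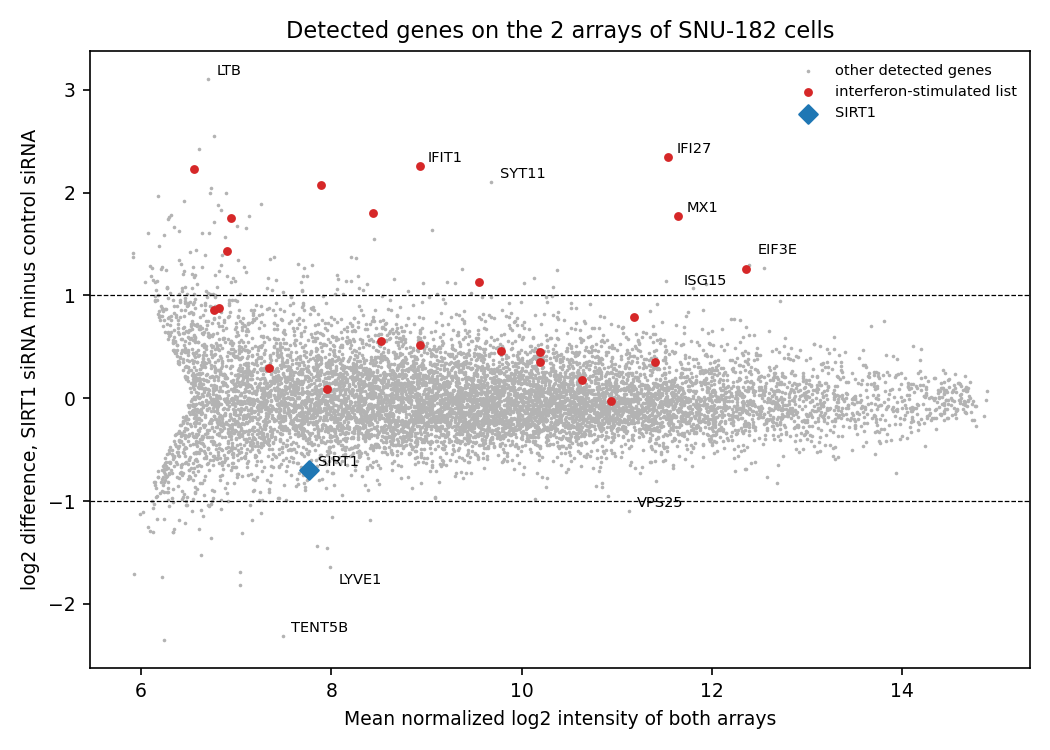
Log2 difference (SIRT1 siRNA minus control siRNA) of each of the 9787 detected named genes against its mean normalized log2 intensity, with the interferon-stimulated list in red and SIRT1 as a blue diamond; dashed lines mark 2-fold. The bright genes IFI27, MX1 and ISG15 lie above the scatter, and SIRT1 lies at -0.70.

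Genes of DNA synthesis were lower together by a small amount. Of 32 detected DNA replication genes 27 were below 0, and none was shown to be 1.5-fold lower or higher. The helicase subunit MCM7 differed by -0.57, the origin-recognition subunit ORC1 by -0.52 and the licensing factor CDT1 by -0.46, while GINS1 (-0.59) was detected with control siRNA only, at least 1.05-fold lower after SIRT1 siRNA. The list median was -0.23, below all 10000 random lists. Genes of the G1/S transition and of mitosis were inside the limits. The 14 detected G1/S genes had a median of -0.13 (13.3rd percentile), none past 1.5-fold, with the phosphatase CDC25A at -0.58, CCND2 at -0.40, E2F3 at -0.34 and CDK6 at 0.46. The 30 mitosis genes had a median of -0.14 (3.17th percentile). Among them CDK1, the main mitotic kinase, was 2.17-fold higher, with 1.12 and 1.35 on its detected probes, and the checkpoint gene MAD2L1 gave 0.60 on its brighter probe and -0.13 on the other, whereas the proliferation marker MKI67 (-0.57) and PLK1 (-0.45) were lower. The 5 detected CDK inhibitors all lay within 1.5-fold (median -0.02), between CDKN2D at -0.37 and CDKN2A at 0.17.

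Antioxidant, growth-signal and ribosome-assembly lists were also lower. The NRF2 target list (16 detected) had a median of -0.27, with 1 random list as low. Its members included SLC7A11, the sulfiredoxin SRXN1 (-0.62) and the transketolase TKT (-0.46), while thioredoxin (TXN) was 0.48 higher. The 14 detected immediate early genes, which answer growth factor signals, had a median of -0.28 (7 random lists as low), with SPRY4 at -0.55, EGR1 at -0.53, JUNB at -0.48 and DUSP5 at -0.43. TGF-beta target genes (13 detected) had a median of -0.24 (0.42nd percentile), with BHLHE40 at -0.56, TGFBI at -0.42, SMAD6 at -0.37 and ID1 at -0.31. The 22 detected MYC targets and ribosome biogenesis genes had a median of -0.21 (0.32nd percentile, but the 2.95th with the trend of neighbouring genes removed), with NOLC1 at -0.47, PPAN at -0.42, BOP1 at -0.40 and ODC1 at -0.39. In these lists only SLC7A11 and SRXN1 passed 1.5-fold.

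Ribosomal protein genes were slightly higher: 22 of 30 detected were above 0 with a median of 0.12, and 6 of 10000 random lists were as high. RPL7 (0.76) passed 1.5-fold, followed by RPL22 (0.54), RPL5 (0.45) and RPL11 (0.24). Many of these genes have near-identical pseudogene copies, so their probe signals are uncertain. The DNA repair list (19 detected) had a median of 0.20 at the 99.2nd percentile. The damage-response kinase ATM, detected only after SIRT1 siRNA, was at least 2.27-fold higher on the background-corrected scale. Its uncorrected signals, 178 and 301, have a smaller ratio. The helicase BLM was at least 1.12-fold and MRE11 at least 1.04-fold higher, and RAD51AP1 differed by 0.75. With genes detected on 1 array at their bounds the list median was 0.09, and under several other settings the list was no longer apart from random lists.

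The p53, FOXO and NF-kB target lists were inside the limits in the main setting. The p53 target list (20 detected) had a median of 0.10 (94.9th percentile): 3 genes were at least 1.5-fold higher and 1 lower. RRM2B, a ribonucleotide reductase subunit detected only after SIRT1 siRNA, was at least 1.56-fold higher on its brightest probe. A second RRM2B probe of nearly the same mean intensity gave a log2 difference of 0.76 against 1.76, so this size depends on the probe. ZMAT3 was 1.67-fold and TP53INP1 1.58-fold higher, and the stress cytokine GDF15 differed by -0.59. The FOXO target list (16 detected) had a median of 0.03 (74.9th percentile), with IGFBP1 lower, FBXO32 at least 1.43-fold and PIK3IP1 1.59-fold higher and TRIB1 at -0.51. The NF-kB target list (14 detected) had a median of -0.21 (1.91st percentile), and its percentile ran from 0.56 to 35.2 over the alternative settings. Its members went both ways. Beside LTB, TNF was detected only after SIRT1 siRNA (at least 1.27-fold higher). The chemokine CXCL8 was 1.65-fold higher on its brighter probe (0.72, against 0.37 on the other), whereas BCL3 differed by -0.65. Among 19 detected partners and substrates of SIRT1 the median was -0.03. The coactivator PPARGC1A was detected only after SIRT1 siRNA, at least 1.68-fold higher, and the histone methyltransferase SUV39H1 was 1.70-fold lower, with NAMPT at 0.49 and FOXO3 at 0.47.

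Metabolic lists did not stand apart as wholes. The cholesterol list (17 detected) had a median of 0.01, with the synthesis genes IDI1 1.78-fold and SC5D 1.67-fold higher and MVK at -0.55. MSMO1 gave 0.67 on its brightest probe, -0.01 on another and -0.50 on one detected with control siRNA only. Fatty acid synthesis genes (13 detected) had a median of 0.00, with the elongase ELOVL6 1.73-fold higher. Medians were -0.05 for 17 detected fatty acid oxidation and PPAR genes, none past 1.5-fold, 0.23 for 6 gluconeogenesis and PGC-1 genes (-0.20 with no detection filter), 0.00 for 27 oxidative phosphorylation genes and -0.10 for 28 glycolysis and HIF target genes. The stress-response gene NDRG1 was 1.81-fold lower and the gluconeogenic enzyme FBP1 1.62-fold higher. The metallothionein list (7 detected) had a median of 0.16, with MT1M 2.06-fold higher. Hepatocyte genes (22 detected) had a median of 0.09 (98.1st percentile): beside CYP1A1, the fibrinogen chain FGG was 1.57-fold higher, APOH differed by 0.46 and APOC3 by 0.43.

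Stress, survival and structural lists lay within the limits as well. Of 20 detected apoptosis regulators (median -0.08), the anti-apoptotic BCL2 was detected with control siRNA only, at least 1.35-fold lower after SIRT1 siRNA, and APAF1 was 1.56-fold higher. The unfolded protein response list (25 detected) and the heat shock list (14 detected) had medians of 0.00 and 0.08, with DNAJB9 1.61-fold higher, and EDEM1 1.52-fold lower beside SLC7A11. The autophagy list (21 detected) had a median of 0.03, with ATG12 (1.75-fold), ATG5 (1.66-fold) and GABARAP (1.60-fold) higher. Mesenchymal genes (11 detected) had a median of -0.15, with MMP3 at least 1.30-fold lower beside ITGA5, and epithelial junction genes (9 detected) also had -0.15, with E-cadherin (CDH1) 1.59-fold lower. Medians were -0.10 for 14 Wnt targets, -0.08 for 12 clock genes, -0.10 for 13 secreted senescence-associated factors, 0.23 for 9 histone genes and -0.10 for 11 genes of the silencing machinery, in which TNRC6A was 1.75-fold higher.

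Markers of other cell types were mostly not detected. Of 14 leukocyte markers 4 were detected, with a median of 0.50 at the 99.6th percentile, which dropped as low as the 71.9th in the alternative settings. CD3D was 2.16-fold higher, LYZ gave 0.73 on its brighter probe and 0.26 on the other, CD14 differed by 0.27 and CD68 by -0.34. The pan-leukocyte gene PTPRC was not detected on either array by any of its probes. A single endothelial marker (ESAM, -0.52) of 8 and a single fibroblast marker (ACTA2, 0.21) of 10 were detected.

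**Figure D3:**
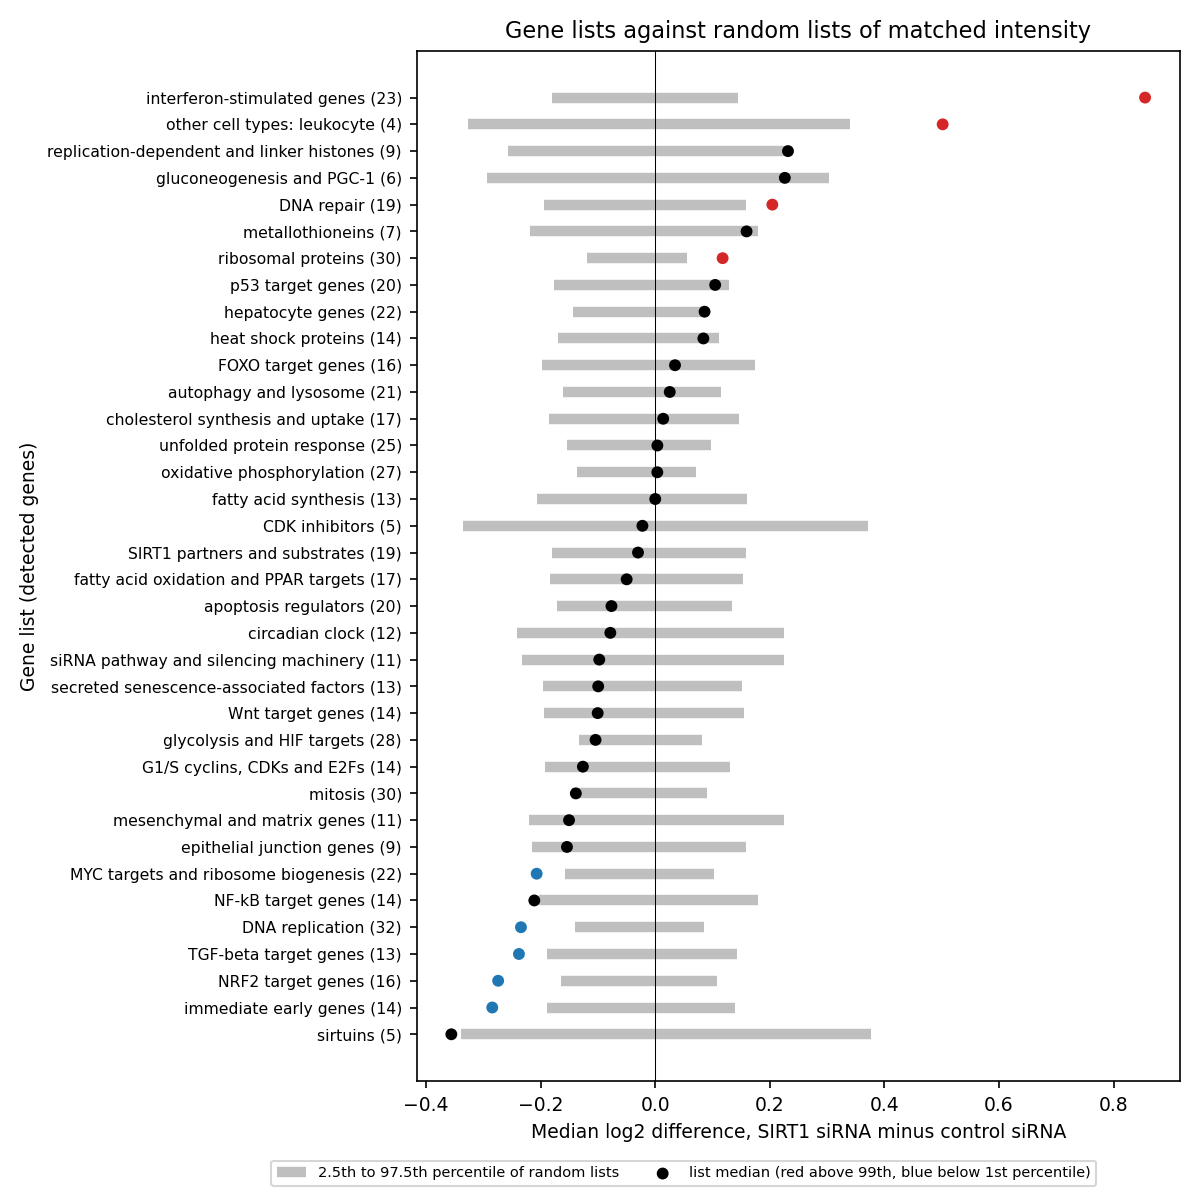
Median log2 difference (SIRT1 siRNA minus control siRNA) of each of 36 gene lists, with the number of detected genes in brackets, as points over grey bars that span the central 95% of 10000 intensity-matched random lists. Points are red above the 99th and blue below the 1st percentile, and the interferon-stimulated list at 0.85 is the farthest from its bar.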

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

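All tests of explanations in this part were chosen after the results were seen. Probes outside the gene comparisons also differed: of 3142 detected probes that were unnamed in the table used, 30 (0.955%) had measured values at least 2-fold higher after SIRT1 siRNA and 21 (0.668%) at least 2-fold lower. Among named genes, each read by 1 probe, the shares were 1.43% and 0.47%. Of the 2623 unnamed probes detected on both arrays, 14 were at least 2-fold higher and 4 at least 2-fold lower. Among unnamed probes detected on both arrays, ILMN_1851376 had the highest log2 difference (1.65) and ILMN_2387385 the lowest (-1.25).

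Interferon-stimulated genes were higher after SIRT1 siRNA. Independent noise of probes, or any 1 of the processing choices run, is argued against as the whole cause: the list's median was at least 0.487 in every setting, and the central 95% of random lists reached no higher than 0.148 in any. Variation between cultures or pools was not measured and stays open. RNA of leukocytes in the SIRT1 siRNA pool stays open: 30.8% of leukocyte markers with a named probe (4 of 13) were detected there, as many as with control siRNA, but these had a median log2 difference of 0.50, and markers near background would not show a small share. Whether the genes answered the SIRT1 siRNA duplex itself or the lower SIRT1 cannot be told apart. There was only 1 array with SIRT1 siRNA and no second SIRT1 sequence to set against it. The control cells were also given an siRNA, so a response of equal size to both siRNAs would not appear as a difference. Both a response to the SIRT1 duplex beyond that to the control siRNA and one to lower SIRT1 may account for the pattern.

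More genes were at least 2-fold higher than lower after SIRT1 siRNA, 79 and 13 with genes detected on 1 array at their bounds. Background correction of dim probes did not make up the whole excess in these counts. Without any correction, and without the interferon-stimulated list, 75.7% of such differences were higher (28 and 9 genes). Nor did that list alone: at the bounds it supplied 10 of the 79 higher genes and 0 of the 13 lower. Without it 84.1% were higher (69 and 13 genes), which follows from those counts and is no separate test. Genes that respond to interferon but are outside the list were not removed. Genes do not vary independently, so no interval is given for these shares. Whether a similar excess would arise between any 2 pools was not tested. A difference between the pools in RNA quality or labelling may remain, and the normalization of the deposited signals hides any shift of the whole distribution.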

How the results depend on the processing

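No paired analysis was possible because each condition had 1 array. Removal of the neighbour trend and the setting with genes detected on 1 array at their bounds were chosen after seeing the data, and the filter on bead standard errors was not run. The median gene differed by between -0.030 and -0.0082 in every setting. The SIRT1 log2 difference was below 0 in every setting: -0.49 without background correction and with the authors' log2 values, which are the same values, and -0.90 with the trend of neighbouring genes removed. Genes at least 2-fold higher and lower numbered 37 and 9 without background correction and with the authors' values, 74 and 15 with an offset of 50, 56 and 9 with detection on both arrays, 79 and 13 at the bounds, and 611 and 374 at 1.5-fold. In all but the last of these every gene counted was also in the main count, so these settings shorten the list. The interferon-stimulated list was above the 99th percentile in every setting, with medians from 0.49 to 0.87. The DNA replication, NRF2, immediate early, TGF-beta and ribosomal protein lists stayed apart in every setting. The DNA repair list was inside the limits without background correction and with the authors' values (0.13), with an offset of 50 (0.17), with detection on both arrays (0.083), with no detection filter (0.090), with the mean of probes (0.090) and at the bounds (0.090). The leukocyte list was inside them with detection p under 0.05 (0.29), with no detection filter (0.059) and with the mean of probes (0.38), and the MYC list with the trend removed (-0.14); the cause was not tested. Other lists crossed the limits in some settings: NF-kB targets (-0.26) and hepatocyte genes (0.11) with detection on both arrays, NF-kB targets with the mean of probes (-0.23; but -0.032 with no detection filter), sirtuins with detection p under 0.05 (-0.49) and with no detection filter (-0.36), histones with no detection filter (0.24) and mitosis with the trend removed (-0.15). Medians of lists inside the limits changed sign in some settings, for the gluconeogenesis list from 0.23 to -0.20 with no detection filter, and for the CDK inhibitor, clock, oxidative phosphorylation, autophagy, apoptosis and silencing machinery lists by less. No 2-fold difference of a named gene changed sign, but sizes moved by more than the SD among probes for 57 of 172 named genes without background correction, 24 with an offset of 50, 22 at the bounds, 12 with the mean of probes and 2 with the trend removed. Of the genes named by size with detection on both arrays, 11 of 15 higher and 4 of 9 lower kept 2-fold without background correction. Signals near background limit all genes detected on 1 array to bounds.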

Other observations

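Gene families defined by the stem of their symbol were examined after the data were seen, 81 families with at least 12 detected members. The RPL family of ribosomal proteins was the 1 family above the 99th percentile of random lists: 38 of 56 detected members were above 0, with a median log2 difference of 0.12. The BCL stem, which joins apoptosis regulators with unrelated B-cell lymphoma genes, had a median of -0.31 over 15 genes, the SH stem -0.21 over 23 and the KCTD family of potassium-channel tetramerisation domain proteins -0.29 over 12, all below the 1st percentile. By chance, 1.62 of 81 families would lie beyond either limit if genes varied independently. With the trend of neighbouring genes removed, the RPL and BCL calls held and those of SH (3.47th percentile) and KCTD (2.66th percentile) did not, while PHF (99.4th percentile), SNORD (99.4th percentile) and RPS (99.1st percentile) came to lie above the limit. The RPL family shares members with the ribosomal protein list, so it is no separate evidence. Zinc finger genes (ZNF, 220 detected) had a median of 0.01 and solute carriers (SLC, 201 detected) -0.05, both within the limits.

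Differences followed the position of genes along the genome, a pattern found and tested after the data were seen. Adjacent genes in the RefSeq order of GRCh38.p14 had more similar differences than in shuffled orders: the Spearman correlation of their log2 differences, without the interferon-stimulated list, was 0.109 over 9729 pairs, and the highest of 1000 orders shuffled within chromosomes was 0.053. The chromosome medians were lowest on the gene-dense chromosomes 22 (-0.14), 19 (-0.10) and 16 (-0.08), and highest on the gene-poor chromosomes 13 (0.10), 4 (0.08) and 18 (0.08). Of 23 chromosomes, 6 lay below and 9 above the central 95% of random draws of as many genes. What makes neighbouring genes differ together was not tested. One candidate explanation among others is a bias with base composition or RNA quality between the 2 pools, which may also move gene lists by a small amount. Removing the part predicted by the 10 genes on each side, 4.28% of the variance, ended the call for 12.5% of the other lists apart from random lists (1 of 8), which leaves this open because so weak a predictor removes only part of any such bias. No genome sequence was used, so base composition itself was not tested.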
